A study of Mus musculus with 4 samples.

How the data were processed

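The data were 4 libraries from the organ of Corti at postnatal day 2, 1 per part (apex and base) and assay (single-cell RNA-seq and single-cell ATAC-seq). Per the labels, tissue was dissected and dissociated, cells were sorted for tdTomato and GFP, and both assays were prepared by droplet barcoding. The labels call the RNA data single-nuclei in a description and speak of loaded cells in the protocol, so barcodes are called cells in RNA and nuclei in ATAC here. Samples were grouped by the part and assay the labels give. The number of animals per library, the sequencing batch and the sort gates were not given in the sources used here.

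The deposited RNA tables hold raw UMI counts per gene and barcode, without normalization, per the file headers and values. They list 476 and 272 barcodes, and how the authors chose these was not given in the sources used here. The deposited ATAC tables hold 1 line per unique fragment and barcode, with a count of read pairs behind it, and list barcodes down to the lowest depths. Cell Ranger 3.0.0 and the mm10 genome are named per the submitters' processing notes, and the RNA file headers name the same version. The aligner settings, annotation release and the program that made the fragments were not given in the sources used here. Every result below was computed anew from the counts.

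RNA barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept. In the apex library, 462 of 476 barcodes passed, with a median of 11188 UMIs and 3428 genes and a median mitochondrial share of 2.38%, out of 6807022 UMIs in all. In the base library 264 of 272 passed, with medians of 12954 UMIs, 3604 genes and 2.55%, out of 4088716 UMIs. Doublet calling by Scrublet, as run in scanpy, called 0 cells in either library. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were taken, and cells of both libraries were clustered together without batch correction by the Leiden method (15 neighbours, resolution 1). Clusters were named from marker lists fixed before the data were examined, where at least 3 markers of a type led the cluster at a log2 ratio of at least 1 in RNA or 0.5 in ATAC, and are called "-like" for this reason. An exception outside these lists left a cluster unnamed, whatever its markers, if Oc90 was among its 10 leading genes. Hair-cell-like cells were clustered again on 10 components. After the results were seen, lists and named genes were also compared within the 1 hair sub-cluster that held several cells of both libraries.

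ATAC barcodes with at least 5000 fragments on chromosomes 1 to 19 and X, and at least 15% of them near gene ends (1 kb to either side of both ends of protein-coding genes), were kept. Of 172832 apex barcodes with 29246801 fragments, 776 passed, with a median of 23710 fragments and 24.6% near gene ends. Of 147775 base barcodes with 18437219 fragments, 264 passed, with medians of 18681 and 26.6%. Over all barcodes the median fragment width was 150 bp in the apex and 76 bp in the base library. Among kept nuclei, short fragments were 35.3% and 38.0% at the median. Nuclei were clustered on 5 kb bins open in 2% to 60% of them, with term weighting and 31 components. Gene activity was the sum of fragments over the gene body with 2 kb to either side. Accessible windows were the 119532 windows of 500 bp with a fragment end in at least 5% of the 1040 nuclei. The gene table given (GRCm38, the assembly of mm10) carries no strand, so promoters were replaced by gene ends. No genome sequence was at hand, so transcription factor motifs were not analysed here.

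In each class, counts were summed over the cells of a library, and CPM were computed. The log2 ratio of apex over base used a pseudocount of 0.5, and its 95% interval came from the exact conditional binomial distribution of Poisson counts. Cells of 1 library are no replicates, so no test between apex and base was run, no p-value is given and no count of changed genes over all genes was made. Shares have exact (Clopper-Pearson) 95% intervals, and a share of 0 has instead the limit that 3 counts give. A gene with 0 counts on a side has a lower bound on its fold against 3 counts summed over the group. A gene was measured with at least 20 counts over both libraries of a class. This held for 7420 genes in RNA and 27396 in ATAC for the hair class of the simulations below, and 9597 and 29377 for the supporting class. Of 31053 RNA gene identifiers, 25200 symbols were found in the gene table, and 24079 of its 34324 genes carried an RNA symbol.

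Gene lists, 36 in all, were fixed before the data were examined. They cover hair cell lists (early, later, bundle, synapse, transcription factors), pathways (Notch, activin with BMP and TGF-beta, hedgehog with retinoic acid, Wnt, FGF, heterochronic, cell cycle), supporting cell lists (tectorial membrane, homeostasis, cytoskeleton) and tonotopic candidates of both sides. Technical lists (immediate early and heat shock, mitochondrial, ribosomal, sex-linked) and markers of 15 cell types complete them. Fewer than 3 erythroid markers were measured in any class, so that list has no value. The ribosomal list took all symbols that start with Rps or Rpl. A list needed at least 3 measured genes. Its median has an interval from 1000 Poisson resamples of the counts and a percentile among 10000 random lists of equal size, matched over 20 expression bins. Members at least 1.5-fold higher on either side were counted. Correlations are Spearman's across genes.

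Named genes followed a rule fixed in advance. In each class and assay it took the 8 genes of largest ratio in each direction among those with at least 50 counts, ranked by the interval bound nearest to 0, without mitochondrial, ribosomal, haemoglobin, sex-linked and unnamed predicted genes. It added the measured tonotopic candidates, 2 members of each other list and the 3 top windows in each direction. Genes outside the rule are said to have been chosen after their values were seen. Some of the genes the rule gave are not reported here.

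The calculation was tested on simulated counts with 200 genes set to differ. At 2-fold, 85.1% (RNA hair class), 85.7% (RNA supporting), 93.9% (ATAC hair) and 91.9% (ATAC supporting) were placed past 1.5-fold on the right side, with 95.7%, 96.9%, 93.9% and 99.0% of intervals covering the true value. At 4-fold, 100% were placed right in each, with coverage of 98.0%, 95.9%, 94.8% and 96.9%. Of genes set equal, 14.5%, 12.3%, 13.3% and 8.68% passed 1.5-fold in the same order, by counting error alone. All 16 genes ranked top were changed ones in each simulation. The simulated counts held Poisson counting error only, the error that the intervals assume. Spread between cells or libraries was left out, so these figures do not cover it.

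Alternatives fixed before the data were examined numbered 70, and 8 were added after seeing the data. They changed the cell filters, clustering, scaling, pseudocount, count minimum, depth, gene region and cell set, 1 at a time, except that the cell filters changed the UMI and mitochondrial limits together and that thinning to 5000 UMIs also left out cells below that depth. A value whose interval held 0 was read as having no side, and many such values turned under some alternative. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, pyarrow 21.0.0 and matplotlib 3.10.9, with the random seed set to 1.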

Results

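The organ of Corti of mice at postnatal day 2 was profiled separately in its apical and basal part. The mice carried Cre recombinase under the control of Fgfr3 with a tdTomato reporter, and GFP under the control of Atoh1. They had been given 200 mg/kg tamoxifen at postnatal day 0. Cells were sorted for tdTomato, which marks cells with Fgfr3 activity such as pillar and Deiters cells, and for GFP, which marks hair cells. Each part gave 1 RNA library and 1 chromatin accessibility library, so nothing was replicated. Hair cells at the base mature ahead of those at the apex, and the comparisons below ask how hair cells and supporting cells of both parts differed in expression and in accessibility. Ratios are apex over base on the log2 scale throughout.

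Hair-cell-like cells made up a like share of both RNA libraries, but they mostly fell in different sub-clusters at apex and base. They were 33 of 462 apex cells (7.14%, exact binomial interval 4.97 to 9.89) and 20 of 264 base cells (7.58%, 4.69 to 11.5) after the sort for tdTomato and GFP. Supporting-cell-like cells were 24.9% of the apex library (115 cells, 21.0 to 29.1) and 21.2% of the base library (56 cells, 16.4 to 26.6), or 12.4% of the base library with at least 3000 UMIs and at most 10% mitochondrial UMIs. Intervals here and elsewhere cover counting error only and not the difference between animals or libraries. Of the 20 base hair-cell-like cells, 15 fell in an outer-hair-cell-like sub-cluster (75.0%, 50.9 to 91.3), which held 2 of the 33 apex cells. Its name rested on 3 outer hair cell markers, and 2 of its 15 base cells held 29 UMIs of Fgf8, an inner hair cell marker. The apex cells were spread over 2 unnamed sub-clusters of 11 cells each, an inner-hair-cell-like one of 6 cells and 3 cells that also carried supporting-cell RNA. Of both unnamed ones, 1 held apex cells alone, and the other held 5 base cells as well. The 3 cells with supporting-cell RNA had a median of 44775 UMIs, against 26867 for the apex class. Scrublet called no doublets, and whether these cells were doublets was not tested otherwise. Inner-hair-cell-like cells were 18.2% of the apex class (6.98 to 35.5) and 0 of 20 at the base, which allows a share of up to 15%. At a finer clustering (resolution 2) 50% of the base hair-cell-like cells took that name, so the share rested on the clustering.

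Among supporting-cell-like cells, Deiters-cell-like cells were 43.5% at the apex (50 cells, 34.3 to 53.0) and 26.8% at the base (15 cells, 15.8 to 40.3), or 53.9% and 41.4% with the stricter cell filter. Pillar-cell-like cells were 11.3% (13 cells, 6.16 to 18.6) and 25% (14 cells, 14.4 to 38.4). Cells like Hensen, Claudius and outer sulcus cells were 16.5% (19 cells) and 37.5% (21 cells), and cells like those of the greater epithelial ridge 28.7% (33 cells) and 10.7% (6 cells). The other cells of the libraries, apex and base, were glial-like (69 and 56), mesenchyme-like (91 and 38), endothelium-like or pericyte-like (61 and 40), melanocyte-like (48 and 6), cycling (30 and 21) and immune-like (6 and 12). A last cluster of 9 and 15 cells, led by Oc90, Vmo1 and Ttr, was left unnamed by the exception for Oc90, whatever name its markers would have given.

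**Figure D1:**
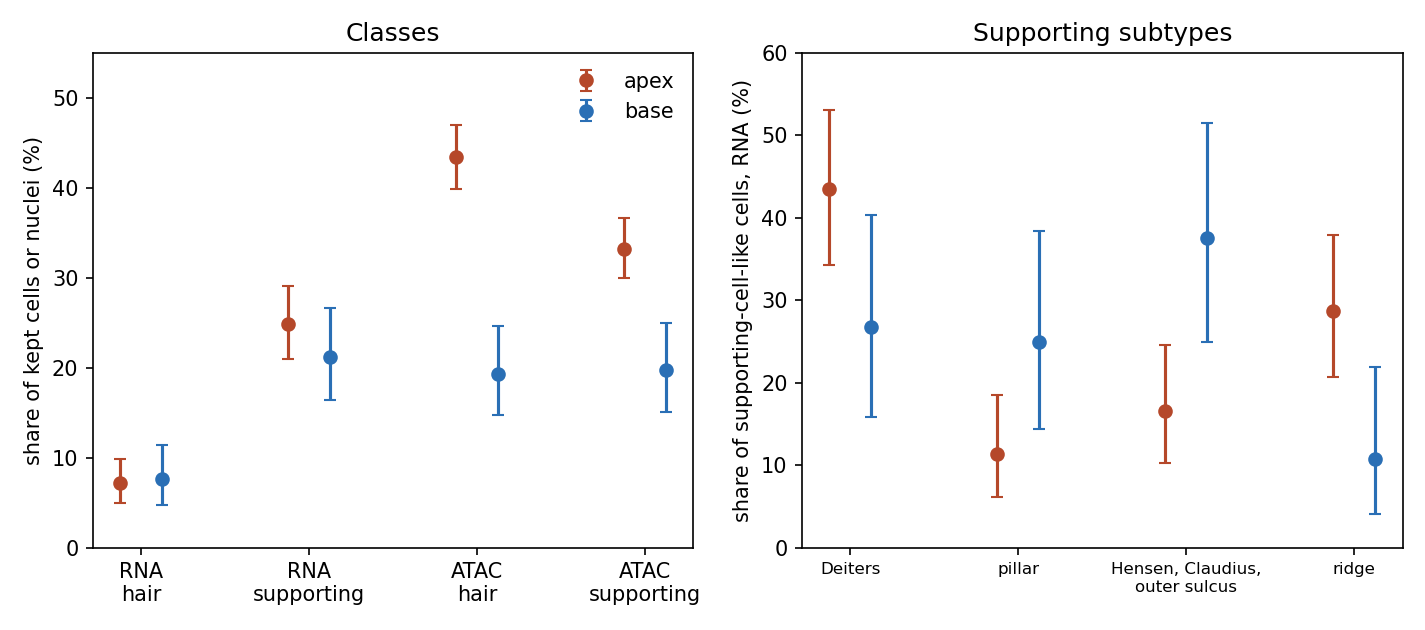
Share of kept cells or nuclei (%, left) and of supporting-cell-like RNA cells (%, right) in the apex (red) and base (blue) libraries, with exact 95% binomial intervals. Hair-cell-like shares were 7.14% and 7.58% in RNA and 43.4% and 19.3% in accessibility, where nuclei of neither class were 23.3% and 61.0%.

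In RNA of hair-cell-like cells, the later hair cell and bundle lists had medians on the base side and the early list on the apex side, although 8 of 16, 19 of 31 and 10 of 13 of their genes differed less than 1.5-fold. The median log2 ratio of the early hair cell list was 0.31 (interval 0.09 to 0.41, percentile 98.4 among random lists), and that of the later list −0.41 (−0.67 to −0.19, percentile 0.15). Within the sub-cluster shared by 11 apex and 5 base cells the sides were not kept: the early list was at −0.28, the later list at 0.41 (0.09 to 0.64) and the bundle list at 0.04. The apex-higher genes of largest size were Nnat, Itih5, Sparc, Mdk, Tectb, Chrng, Npy and Stmn1. The base-higher ones were Pla2g7, Dapl1, Nfix, S100a10, Pkhd1l1, Nbas, Hist1h2bc and Lmod3. Nnat, an imprinted gene for a small membrane protein (mm10 chromosome 2, 157560078 to 157562525), stood at 1572 CPM in the apex and 3.55 CPM in the base (1459 and 2 UMIs, log2 ratio 8.47, 6.94 to 11.84). It had UMIs in 22 apex cells and in 1 base cell of the class. Chrng, the fetal subunit of the muscle acetylcholine receptor, was at 228.5 and 5.32 CPM (212 and 3 UMIs, 5.21, 3.86 to 7.71), with 0 UMIs in glial-like cells of either library. Mdk, which encodes the growth factor midkine, had 210 and 2 UMIs (5.68, 4.12 to 9.05). Stmn1, which encodes the microtubule regulator stathmin, was at 552.8 and 33.7 CPM (4.0, 3.38 to 4.78). In the shared sub-cluster Nnat had 87 and 2 UMIs and Chrng 28 and 1, but Stmn1 was at 94.0 and 95.8 CPM (24 and 15 UMIs). Itih5, for a hyaluronan-binding matrix protein, had 144 UMIs in the apex and 0 in the base, which made it at least 29.2-fold higher, and 52 and 0 UMIs without 3 cells of mixed content. Sparc (186 and 1 UMIs), Tectb (144 and 1) and Npy (67 and 0) came almost wholly from the 3 mixed cells, and all 67 Npy UMIs from 1 of them.

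On the base side, Pla2g7, which encodes an enzyme that breaks down platelet-activating factor (chromosome 17, 43567994 to 43612202), was at 2.15 CPM in the apex and 216.3 CPM in the base (2 and 122 UMIs, log2 ratio −6.33, interval −9.71 to −4.76). Nfix, which encodes a transcription factor of the nuclear factor I family (chromosome 8, 84704712 to 84801238), had 1 and 56 UMIs (−5.95, −11.85 to −3.99). Pkhd1l1, whose protein coats the surface of hair bundles, had 19 and 91 UMIs (−2.95, −3.77 to −2.25). Lmod3, an actin nucleator gene of both the later and the outer hair cell list, had 25 and 87 UMIs (−2.5, −3.22 to −1.86). Dapl1 had 5 and 123 UMIs (−5.21), S100a10 21 and 113 (−3.12), Nbas 160 and 490 (−2.33) and Hist1h2bc, a histone gene, 120 and 342. The base UMIs of these 8 genes lay mostly in the outer-hair-cell-like sub-cluster of 15 base and 2 apex cells: all 122 of Pla2g7, all 56 of Nfix, 86 of 87 of Lmod3 and 285 of 342 of Hist1h2bc. In the shared sub-cluster Pla2g7 and Nfix had 0 UMIs in both libraries.

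**Figure D2:**
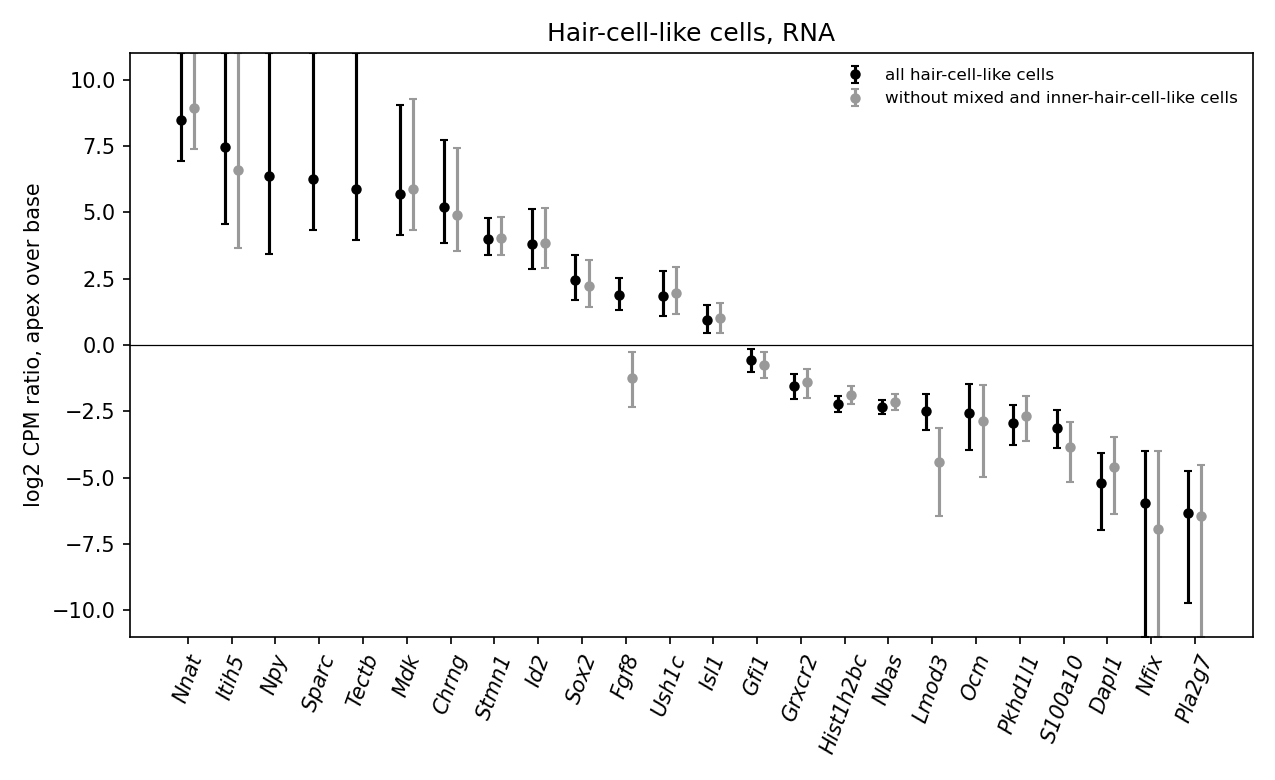
Log2 ratio of CPM, apex over base, for named genes in hair-cell-like cells (points, with 95% counting intervals clipped at the axis edges; genes with at least 20 UMIs). Black points use the 33 and 20 cells, and grey ones leave out the mixed and the inner-hair-cell-like cells, where Fgf8 turned from 1.87 to −1.24; points for genes with 0 UMIs on a side rest on the pseudocount.

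Of 13 measured early hair cell genes, 2 were at least 1.5-fold higher in the apex, 1 in the base and 10 neither. Sox2, a factor of prosensory cells, was at 138 and 24.8 CPM (log2 ratio 2.43) but at 47.0 and 63.9 CPM in the shared sub-cluster (12 and 10 UMIs), and Ebf1 at 1055 and 831.4 CPM (0.34). Of 16 later genes, 2 were higher in the apex, 6 in the base and 8 neither. Ocm, which encodes the calcium buffer oncomodulin, had 8 and 30 UMIs (−2.56). The bundle and mechanotransduction list had a median of −0.28 (−0.40 to −0.14, percentile 0.17), with 3 of 31 genes apex-higher, 9 base-higher and 19 neither. Within it, Grxcr2, for a protein of the stereocilia base, was at −1.55, and Ush1c, which encodes harmonin, was at 1.86. In the shared sub-cluster Grxcr2 was at −0.16 (25 and 17 UMIs) and Ush1c at 0.14 (22 and 12 UMIs). Of 16 synapse and channel genes, 4 were apex-higher, 3 base-higher and 9 neither (median −0.27). Chrna10, a receptor subunit for efferent input, was at −0.65, or 0.41 in the shared sub-cluster (70 and 32 UMIs, −0.20 to 1.07). Cabp2, a calcium sensor of the inner hair cell synapse, was at 2.43 with all cells (57 and 6 UMIs) and had 5 and 6 UMIs without mixed and inner-hair-cell-like cells, too few to be measured. The hair cell transcription factor list was near 0 (median 0.08, percentile 72.3, 13 of 16 neither), with Isl1 at 0.95 and Gfi1 at −0.59. In the shared sub-cluster this list was at −0.32 (−0.58 to −0.11), with Isl1 at −0.47 (19 and 16 UMIs) and Gfi1 at −0.88. Outer hair cell markers had a median of −0.37 (3 of 9 base-higher, 0 apex-higher). Inner hair cell markers had a median of 0.54, which turned to −1.27 without mixed and inner-hair-cell-like cells. Without those cells the early list was at 0.44 and the later list at −0.51 (−0.90 to −0.35). With cells thinned to 5000 UMIs the later list was at −0.18, the bundle list at −0.13 and the outer hair cell markers at 0.0515, and with a mean of per-cell CPM the early list was at 0.49 and the later list at −0.15.

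The activin, Wnt, FGF and Notch lists in hair-cell-like cells had medians on the apex side, and the hedgehog and retinoic acid list did not. The Notch list was at 0.70 (7 of 13 apex-higher, 0 base-higher) and at 0.18 without the mixed cells (6 of 7 neither), and its top gene, Hey1, had 29 UMIs in the apex and 0 in the base (at least 5.88-fold higher) but 3 and 0 without them. The activin, BMP and TGF-beta list was at 1.45 (8 of 11 apex-higher, 2 base-higher) and at 0.72 without them. Its members Id2 (209 and 14.2 CPM, log2 ratio 3.80) and Id3 (395.5 and 42.6 CPM, 3.19), which encode inhibitors of basic helix-loop-helix factors, were at 3.76 and 2.78 without the mixed cells, and at 2.23 and 2.05 in the shared sub-cluster. The Wnt list was at 1.67 (4 of 5 apex-higher, 0 base-higher), with the receptor gene Fzd9 at 2.09 and Sfrp1, for a secreted Wnt inhibitor, at 4.51, or 2.65 without the mixed cells. In the shared sub-cluster the activin list was at 1.07 (0.45 to 1.66). There the Wnt list was at −0.04 (−0.71 to 0.92), the Notch list at −0.19 (−0.47 to 0.21) and Fzd9 at −0.20 (13 and 9 UMIs). The FGF list was at 1.40 (4 of 7 apex-higher, 1 base-higher), and at 0.46 in the lowest of its alternatives. Its Fgf8 was at 1.87 with all cells and at −1.24 without mixed and inner-hair-cell-like cells. The latter value rested on 13 apex UMIs in 2 cells and 29 base UMIs in 2 cells. Of 3 hedgehog and retinoic acid genes, the retinol transporter gene Stra6 was at −3.20 and Crabp2, for a retinoic-acid-binding protein, at 3.12 (median −0.36). Of 5 cell cycle genes, 3 were apex-higher and 1 base-higher (median 0.94), with the inhibitor genes Cdkn1a at 2.98 (7 and 4 UMIs in the shared sub-cluster) and Cdkn1b at 1.39. The base-enriched candidates of earlier tonotopic work, A2ml1 (−2.39), Bmp7 (−1.43) and Efnb2 (−1.05), were all base-higher (median −1.43). In the shared sub-cluster they had too few UMIs to be measured (4 and 8, 7 and 3, and 4 and 5), so their side there is not known. Fewer than 3 genes of the apex-enriched candidates and of the heterochronic list were measured.

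Genes of other cell types marked the mixed cells in this class. Medians were 3.82 for Deiters markers (3.63 with genes at 0 set to their bound), 2.05 for pillar markers, 3.35 for inner phalangeal markers, 5.87 for ridge markers (4.87 at the bound), 0.37 for Hensen markers, 4.21 for tectorial membrane genes and 1.90 for the supporting cell cytoskeleton. Prss23, a Deiters marker, had 56 UMIs in 4 apex cells and 0 in the base (at least 11.3-fold higher), and Col2a1 had 51 and 1 UMIs. Without the mixed cells the pillar list was at 1.18 and the cytoskeleton list at 0.94, and the tectorial list was no longer measured. In the shared sub-cluster the pillar list was at 0.44 (−0.18 to 0.80) and the cytoskeleton list at −0.005 (−0.20 to 0.36). The homeostasis list was at 0.42, and its S100a1 was at 1.19 with all cells and at 0.09 without mixed and inner-hair-cell-like cells. Neuron markers, which hair cells share in part, were at 0.85, with Nefl at 0.999, or −0.0816 without inner-hair-cell-like cells. In the shared sub-cluster the neuron markers were at −0.32 (−0.63 to 0.14) and Nefl at −0.10. The mitochondrial list was at −0.59 (7 of 13 base-higher, 0 apex-higher), the sex-linked list at −0.52 and the ribosomal list at 0.03. The immediate early and heat shock list was at 0.46, with Fos at 0.96 and Hspa8 at −0.87, and at −0.0595 with thinned cells. In the shared sub-cluster this list was at −0.50 (−0.80 to −0.29), with Fos at −0.38 and Hspa8 at −0.76. Median UMIs per cell of the class were 26867 in the apex and 31018.5 in the base.

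In supporting-cell-like cells, Crabp2, Nr2f2 and 5 of 8 heterochronic genes were higher in the apex, while 6 of 13 FGF pathway genes, 7 of 16 tectorial membrane genes and 7 of 10 pillar markers (5 of 10 within pillar-like cells) were higher in the base. The class mixed its subtypes in different shares at apex and base, so values are given within subtypes as well. Crabp2, for a retinoic-acid-binding protein (chromosome 3, 87948693 to 87953372), was at 198 and 24.2 CPM (402 and 20 UMIs, log2 ratio 3.0, 2.39 to 3.76). Its ratio was 3.47 in Deiters-like, 3.44 in pillar-like, 1.64 in Hensen-like and 2.63 in ridge-like cells. Nr2f2, a nuclear receptor gene (chromosome 7, 70351946 to 70366746), was at 96.3 and 4.84 CPM (195 and 4 UMIs, 4.15, 2.93 to 6.20), with 3.54, 3.72 and 2.13 in the first 3 of these subtypes and 73 and 0 UMIs in ridge-like cells. Nnat was higher in the apex here too (400 and 16 UMIs, 3.31), with 2.42 in Deiters-like and 4.03 in pillar-like cells. The other top apex genes followed single subtypes or cells. Calb1 (698 and 24 UMIs) and Upp1 (134 and 1) lay in ridge-like cells and Fabp7 (581 and 18) in Deiters-like cells. Dct (329 and 1), Ccer2 (235 and 4) and Grp (62 and 0, at least 8.42-fold higher) came mostly from 1 cell each, with 99.4%, 57.0% and 85.5% of their apex UMIs.

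Most base UMIs of the top base genes lay in 1 or 2 subtypes, whose values are given. Npy was at 560 and 4311 CPM (log2 ratio −2.94, −3.04 to −2.85) and at −1.95 within pillar-like cells, while Deiters-like cells had 31 and 0 UMIs of it. Calb2, for the calcium buffer calretinin, had 28 and 233 UMIs (−4.33) and was at −3.45 in pillar-like cells. Lgr6, a receptor gene for Wnt enhancers, was at −2.93 (−1.82 in pillar-like cells), and Fam83a at −2.88 (−2.69 in pillar-like, −2.13 in Deiters-like cells). Scg2 was at −2.38 and the carbonic anhydrase gene Car12 at −2.54, with −1.28 and −1.50 in Hensen-like cells. Mal was at −4.01 and Fxyd6 at −2.85, with −3.42 and −2.42 in Hensen-like and −5.81 and −2.92 in ridge-like cells. All 16 top genes stayed at least 1.5-fold apart, on the same side, when the subtypes were weighted equally. Nfix, chosen after its values were seen, was base-higher in this class as well (136 and 221 UMIs, −1.99), with −3.50 in Deiters-like, −4.84 in pillar-like, −0.90 in Hensen-like and −1.17 in ridge-like cells. In mesenchyme-like cells Nfix had 466 and 235 UMIs (−0.14, −0.37 to 0.09).

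**Figure D3:**
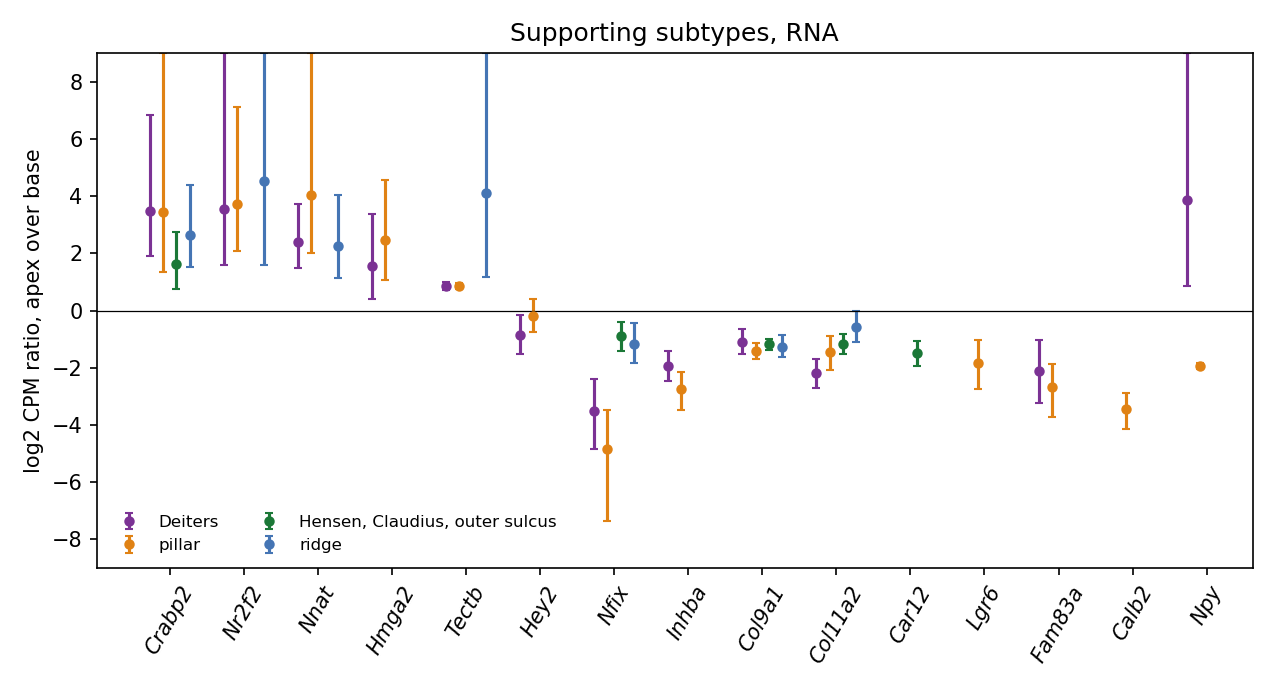
Log2 ratio of CPM, apex over base, within each supporting subtype (points, with 95% counting intervals clipped at the axis edges; shown where a subtype had at least 20 UMIs, and resting on the pseudocount where a side had 0). Crabp2 lay between 1.64 and 3.47 and Col9a1 between −1.41 and −1.09 in all 4 subtypes.

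Of 13 FGF pathway genes, 2 were apex-higher, 6 base-higher and 5 neither (median −0.58, −0.65 to −0.20, percentile 0.02). Fgfr2 was at −2.13 and −1.12 in Hensen-like cells, and Fgf3, a Deiters marker, at 2.26. The list was at −0.68 in Deiters-like, 0.03 in pillar-like, −0.28 in Hensen-like and −0.87 in ridge-like cells, and at −0.20 with a mean of per-cell CPM. The heterochronic list, of genes under let-7 and LIN28 control, was at 0.97 (0.59 to 1.5, percentile 100), with 5 of 8 genes apex-higher and 0 base-higher. Its Hmga2 was at 56.8 and 10.9 CPM (115 and 9 UMIs, 2.31, 1.41 to 3.55), with 1.57 in Deiters-like and 2.45 in pillar-like cells, and H19 at 2.93. The list was at 0.30 in Deiters-like, 0.55 in pillar-like and 1.42 in ridge-like cells (0.62 at the bound). The tectorial membrane list was at −0.51 (−0.58 to −0.36, 2 of 16 apex-higher, 7 base-higher), with −0.65, −0.59, −0.99 and 0.00 in Deiters-like, pillar-like, Hensen-like and ridge-like cells, and at −0.19 with cells of at least 3000 UMIs and at most 10% mitochondrial UMIs. Col9a1, for a collagen of the tectorial membrane, was at 416 and 1381 CPM (−1.73), and Col4a4 at −2.40. Tectb, for the matrix protein beta-tectorin (chromosome 19, 55180726 to 55196313), was at 2835 and 1877 CPM (0.60, 0.51 to 0.68), with 0.85 in both Deiters-like and pillar-like cells.

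Candidates from earlier tonotopic work were set beside these. The apex-enriched list had a median of 0.53 (−0.14 to 0.66, percentile 99.7, 2 of 5 apex-higher, 1 base-higher), with Hmga2, Tectb and Igf2bp1 (0.53, −0.18 to 1.35) positive and Hey2 (−0.61, −1.02 to −0.18) negative. Fst had no side at this depth (−0.33, −0.71 to 0.06) and was at 2.96 with the stricter cell filter of at least 3000 UMIs, and Igf2bp1 was at −0.38 with a mean of per-cell CPM. The base-enriched list was at −0.56, with Inhba, which encodes an activin subunit, at 48.9 and 253 CPM (−2.37, −2.73 to −2.02), Bmp7 at −0.56 and Efnb2 at 0.13. Inhba was at −1.94 in Deiters-like, −2.75 in pillar-like and −1.63 in Hensen-like cells. The activin, BMP and TGF-beta list as a whole was at 0.13 (13 of 18 neither), with Fstl1, for a follistatin-like protein, at 1.19. The Notch list was at 0.20 (0.02 to 0.38, 3 of 16 apex-higher, 1 base-higher), with Rfng at 2.17 and Notch3 at 1.36, and at −0.10 in Deiters-like cells alone and −0.0256 with a mean of per-cell CPM. The hedgehog and retinoic acid list was at −0.08 (3 of 10 apex-higher), although Crabp1 (2.67) and Crabp2 were among its largest values. The Wnt list was at −0.14 (4 apex-higher and 4 base-higher of 17), and at −0.45 in Deiters-like cells alone (5 of 10 base-higher, 0 apex-higher). Lgr5 was at −1.05, but Lgr5 in Deiters-like cells alone was at 0.11.

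The cell cycle list was at −0.17 (3 of 9 apex-higher, 0 base-higher), with Ccnd3 at 0.97 and Cdkn1c at −0.57, and at 0.21 with a mean of per-cell CPM. The homeostasis list was at −0.03 (4 apex-higher and 5 base-higher of 13), with the ion transport genes Kcnj10 at −2.88 and Slc12a2 at 1.92. The cytoskeleton list was at 0.11, yet 4 of its 15 genes were base-higher and 0 apex-higher, among them Tubb2a (−1.61) and Map1b (−1.38). The early hair cell list was at 0.33 (3 of 7 apex-higher, 1 base-higher), with Atoh1 at 46 and 2 UMIs, and Pou4f3 had 28 UMIs in 4 apex cells and 0 in the base (at least 3.80-fold higher). The later list was at 1.31 over the 4 genes measured, Atp2b2, Calb1, Calb2 and Sri, of which 2 were apex-higher and 1 base-higher, and at 0.0173 with a minimum of 10 UMIs. Bundle genes were at 0.04 (Tmie 1.87, Fscn1 −0.85, or 0.0671 with thinned cells) and synapse genes at 0.31 (Syt1 1.51). Hair cell transcription factors were at 0.33, and at −0.0192 with equal weight for the subtypes.

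Marker medians in this class were −0.96 for pillar cells (7 of 10 base-higher, Smagp −1.64, and −0.57 within pillar-like cells), 0.15 for Deiters cells (Pdzk1ip1 1.37), 0.93 for inner phalangeal cells (Cdh4 1.46, and −0.18 for the list with a mean of per-cell CPM), −0.15 for Hensen cells and −0.13 for the ridge. They were −0.80 for inner and −0.31 for outer hair cells, 0.11 for glia and −0.62 for mesenchyme. Lum, a mesenchyme marker, was at −0.63, but at 1.38 in Deiters-like cells alone. The immediate early and heat shock list was at −0.37 (3 of 15 base-higher, 0 apex-higher), with Fos at −0.63. The mitochondrial list was at −0.38, the sex-linked list at −0.21 and the ribosomal list at 0.23. Median UMIs per cell were 15979 and 11430.

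Apex-base ratios of hair-cell-like and supporting-cell-like cells were weakly related at these counts. Spearman's rho across 6426 genes was 0.09, and genes are not independent replicates. It was 0.046 with a mean of per-cell CPM and 0.123 with a minimum of 50 UMIs. Counting error lowers such a rho, as resampled counts gave 0.045 to 0.081, so a closer relation is not excluded. Against glial-like cells, the hair-cell-like ratios gave a rho of 0.027 (4728 genes).

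**Figure D4:**
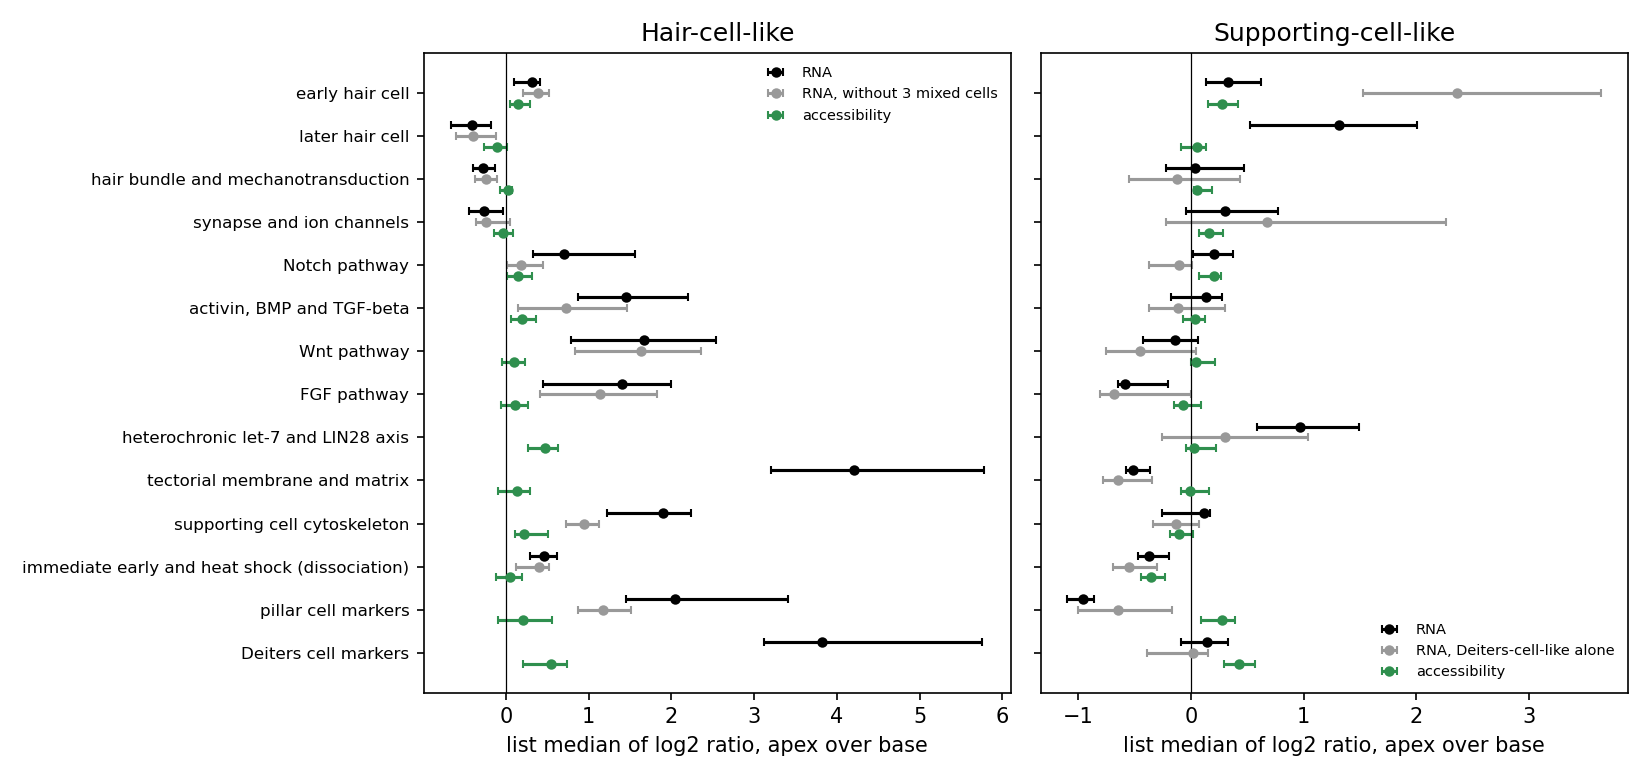
Median log2 ratio, apex over base, of fixed gene lists in hair-cell-like (left) and supporting-cell-like (right) cells or nuclei, with 95% intervals from resampled counts. Black is RNA, grey RNA without the 3 mixed cells (left) or in Deiters-like cells alone (right), and green accessibility; the later hair cell list was at −0.41 in RNA and −0.11 in accessibility.

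In the accessibility libraries, hair-cell-like nuclei made up 337 of 776 apex nuclei (43.4%, 39.9 to 47.0) and 51 of 264 base nuclei (19.3%, 14.7 to 24.6) after the same sort. Supporting-cell-like nuclei were 258 (33.2%, 29.9 to 36.7) and 52 (19.7%, 15.1 to 25). Nuclei of neither class were 181 (23.3%, 20.4 to 26.5) and 161 (61.0%, 54.8 to 66.9). The shares of both classes were thus lower in a base library with more other nuclei, and need not reflect the make-up of the tissue. Of the hair-cell-like clusters, 1 held 38 of the 51 base nuclei and 77 apex ones, a cluster led by Otof and Espnl 82 apex and 7 base nuclei, and the others 72 and 3, and 106 and 3. The Deiters-like supporting clusters held 100 and 8, and 21 and 14 nuclei. The ridge-like cluster held 15 and 18, and both other supporting clusters 73 and 7, and 49 and 5. The Deiters-like cluster of 21 and 14 nuclei, with 14 of the 22 base Deiters-like nuclei, had a less sure name. Its gene activity gave a Spearman's rho of 0.205 with the Deiters-like RNA cluster, 0.184 with the ridge-like and 0.179 with the pillar-like one. Unnamed nuclei were 5.41% of the apex library (42 nuclei, 3.93 to 7.25) and 26.9% of the base library (71 nuclei, 21.6 to 32.7), and 61 of the base ones formed a cluster led by Fgfr2.

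In hair-cell-like nuclei, list medians of accessibility over genes lay nearer 0 than those of RNA for the lists measured in both, and heterochronic genes leaned most to the apex among the pathway lists. The heterochronic list was at 0.47 (0.27 to 0.63, percentile 100), with 3 of 12 genes apex-higher, 0 base-higher and Hmga2 at 0.59 (986 and 87 fragments). The early hair cell list was at 0.15 (0.04 to 0.30, percentile 95.9), with the Notch ligand gene Dll3 at 1.02. It was at −0.0152 over gene ends alone and at −0.0943 in the cluster with most base nuclei. The later list was at −0.11 (−0.26 to 0.01, percentile 11.97), with 18 of 19 genes neither, and at 0.12 over gene ends alone. Tmc1, a transduction channel gene of that stage, was at −0.85 (791 and 190 fragments) over the gene body, while over gene ends alone the base had 0 fragments. Grxcr1, a bundle gene, was at −0.93 (1083 and 276 fragments), Pou4f3, a hair cell transcription factor gene, at −0.56, Chrna10 at −0.50 and Isl1 at 0.58. The Notch list was at 0.14 and the activin, BMP and TGF-beta list at 0.20 (5 of 20 apex-higher, 0 base-higher), with Fst, which encodes follistatin, at 1.94 (157 and 5 fragments). Apex-enriched tonotopic candidates were at 0.38 (2 of 6 apex-higher) and base-enriched ones at −0.22 (2 of 5 base-higher, A2ml1 −1.15). Deiters markers were at 0.54 (4 of 12 apex-higher), glial markers at 0.43 and immune markers at 0.34. The other lists lay between −0.17 and 0.26. The largest single genes were Gabrr1 (198 and 3 fragments, 2.92), Pax8 (124 and 2), Myo1a (91 and 1), Kcnmb1 (88 and 1) and Ephx3 (61 and 0, at least 2.72-fold higher) on the apex side. On the base side they were led by Scn7a (52 and 38) and Muc16 (92 and 57), and 5 of the 8 base-side genes had over 50% of their base fragments in 1 nucleus.

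Supporting-cell-like nuclei showed the largest list value for apex-enriched tonotopic candidates (median 0.64, 0.47 to 0.77, percentile 100, 3 of 6 apex-higher). Tectb was at 1.73 (696 and 39 fragments, 1.28 to 2.25), Hmga2 at 0.78 and Lin28b, for a regulator of let-7, at 0.77. The Notch list was at 0.20 (percentile 99.9), with Lfng at 0.76 and Hes5 at 0.66. Fgfr3, the gene behind the sort for tdTomato, was at 0.89 (1535 and 156 fragments). Deiters markers were at 0.43 (5 of 12 apex-higher, 0 base-higher) and pillar markers at 0.28. The early hair cell list was at 0.28 (percentile 99.4). The immediate early and heat shock list was at −0.35 (−0.44 to −0.23, 3 of 16 base-higher), with Fos at −0.61 and Zfp36 at −0.81. The heterochronic list was at 0.03, the FGF list at −0.07 and the tectorial list at −0.01. Markers were at 0.02 for cycling cells, 0.19 for the stria, 0.05 for endothelium, 0.48 for immune cells, 0.27 for neurons and −0.24 for glia (0.0937 in Deiters-like nuclei alone). Lax1 (109 and 1 fragments) and Mroh2b (116 and 2) were among the genes of largest size at the apex. Of the 8 at the base, 7 had over 50% of their base fragments in 1 nucleus, among them Ifi208 (38 and 57, −2.99), which was at 1.60 without the nuclei over 100000 fragments.

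Among windows of 500 bp, those of largest size in hair-cell-like nuclei lay on the base side 8452 bp from Grxcr2 (chromosome 18, 42007501 to 42008000), with 43 and 44 fragment ends (log2 ratio −3.03), and near Zfp503 (chromosome 14, 21941501 to 21942000), with 26 and 27. On the apex side they lay in Ccdc93 (chromosome 1, 121452501 to 121453000, 154 and 0 ends, at least 6.43-fold higher) and Col7a1 (chromosome 9, 108960001 to 108960500, 148 and 0). In supporting-cell-like nuclei a window in the cannabinoid receptor gene Cnr1 (chromosome 4, 33941501 to 33942000) had 167 and 0 ends, and a window in Taf3 (chromosome 2, 10021001 to 10021500) had 27 and 44 (−3.09). Windows had to be open in at least 5% of all 1040 nuclei, and the base classes held 51 and 52 nuclei. Windows open in these alone could hardly pass, so the filter favoured apex-side windows with 0 base ends.

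RNA and accessibility ratios were weakly related, and whether the classes differed in this was not tested. Spearman's rho between them was 0.155 across 6896 genes in the hair-cell-like class and 0.034 across 9007 genes in the supporting-cell-like class. The hair-cell-like value was 0.086 over gene ends alone and 0.179 with a minimum of 50 counts. Counting error lowers such values. With the classes crossed rho was 0.039 and 0.047. Of the genes named in RNA, 39 of 51 had the same sign in hair-cell-like nuclei (76.5%, 62.5 to 87.2), and 32 of 59 in supporting-cell-like nuclei (54.2%, 40.8 to 67.3). These ranges treat genes as independent, which they are not, and may be too narrow. Where both intervals left out 0, 18 of 20 hair genes had 1 sign, among them Nnat, Chrng, Stmn1, Id2, Id3 and Isl1 at the apex and Pla2g7, Nfix, Grxcr2, Pkhd1l1 and Chrna10 at the base. Sox2 and Nefm were the exceptions. In the supporting class 11 of 18 did, among them Nr2f2, Hmga2, Tectb and Slc12a2 at the apex and Car12, Lgr6 and Tubb2a at the base, while Crabp1, H19, Lgr5, Hey2, Bmp7, Syt1 and Col4a4 had opposite signs. Over gene ends alone, accessibility of Bmp7 was at −0.41, on the side of its RNA, and that of Lgr5, at −0.00794, showed no side. For comparison, the hair-to-supporting difference gave a rho of 0.595 between RNA and accessibility in the apex (9207 genes) and 0.5002 in the base (7199 genes).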

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

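All tests in this part were chosen after the results were seen.

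Some gene lists leaned to opposite sides in the hair-cell-like and supporting-cell-like classes, with intervals that left out 0 on both sides. In RNA these were the later hair cell list (−0.41 and 1.31), the FGF list (1.40 and −0.58), the tectorial membrane list (4.21 and −0.51), the immediate early and heat shock list (0.46 and −0.37) and the pillar markers (2.05 and −0.96). In accessibility it was the hedgehog and retinoic acid list (0.17 and −0.11). For each of them the difference was not tested. Several did not hold under other settings: the later list of the supporting class was at 0.0173 with a minimum of 10 UMIs, and the immediate early list of the hair class at −0.0595 with thinned cells. In the hair sub-cluster shared by both libraries the immediate early list was at −0.50 (−0.80 to −0.29) and the later list at 0.41 (0.09 to 0.64). Pillar markers there were at 0.44 (−0.18 to 0.80). The FGF list of the hair class ranged from 0.46 to 1.40 over its alternatives. The hedgehog list was at −0.0268 in 1 hair-cell-like cluster and at 0.00998 in Deiters-like nuclei. The tectorial list of the hair class was not measured without the 3 mixed cells. Signal also lay in data that the comparisons did not use. Kept nuclei held 5564 apex and 2011 base fragments on the Y chromosome. The largest barcode with too low a share near gene ends had 144871 fragments in the apex and 726923 in the base library.

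The first pattern weighed was the set of 8 genes highest in apex hair-cell-like cells over base ones. For Sparc, Tectb and Npy, 96.7% of the apex UMIs (384 of 397) lay in the 3 cells that mix hair and supporting cell RNA, so these cells may account for them. For Nnat, Itih5, Mdk, Chrng and Stmn1 the mixed cells were excluded as the whole cause, since without them the lowest lower bound of the 5 log2 ratios was 3.28, and so was free RNA: Sparc, at 2821 CPM in apex glial-like cells, was at 6.32 CPM in the remaining apex cells of the class, against 613 CPM of Stmn1. In the sub-cluster shared by 11 apex and 5 base cells the lowest lower bound for Nnat and Chrng was 1.5. Another mix of hair cell sub-clusters was thus not enough for these counts, but the bound covers counting error only. Nnat had UMIs there in 5 apex cells and 1 base cell, and Chrng in 7 and 1. A finer mix of cells within the sub-cluster therefore stays open for both genes. Another mix of the sub-clusters stays open for Stmn1, at −0.0462 in the shared one (−1.02 to 1.01), and for Itih5 and Mdk, with at most 14 UMIs. A difference between apex and base in vivo stays open and untested against the library, since each part had 1 library.

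The second pattern was the higher early and lower later list in apex hair-cell-like cells. Another mix of hair cell sub-clusters may account for both lists, since in the shared sub-cluster the early list was at −0.28 (−0.46 to −0.00333) and the later list at 0.41 (0.09 to 0.64), but sub-clusters made from expression may follow maturity too. A larger share of inner-hair-cell-like and mixed cells at the apex stays open, although the later list was at −0.51 (−0.90 to −0.35) without them, because the removal took 9 apex and 0 base cells and left inner hair cell markers at −1.27. A larger weight of deep cells was excluded as the whole cause for the early list, which was at 0.49 from the mean of per-cell CPM. It could not be excluded for the later list, where this gave −0.15. The mean of per-cell CPM leaves the depth of each cell as it was, so unequal depth itself stays open. With cells thinned to 5000 UMIs the later list was at −0.18. A more mature state of the base hair cells would also be expected in accessibility, where the later list was at −0.11 (−0.26 to 0.01), an interval that reaches 0 and leaves it open, and at 0.12 over gene ends alone.

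The third pattern was the set of 16 genes with the largest ratios in supporting-cell-like cells. With equal weight for the 4 subtypes, 16 of 16 stayed at least 1.5-fold apart the same way. This excluded another mix of these subtypes as the whole cause, except for Dct, Ccer2 and Grp. The RNA of 1 cell stays under any weighting, so the weighting could not decide for them. Dct, Ccer2 and Grp may reflect single cells, since at least 57.0% of their apex UMIs lay in 1 cell. For the other genes, the part of the cochlea and the library stay open together.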

How the results depend on the processing

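The 8 alternatives added after seeing the data were those on mixed cells, inner-hair-cell-like cells, equal subtype weight, Deiters-like cells or nuclei alone, 1 hair-cell-like cluster, deep nuclei and windows at a higher depth; the others were planned. No paired analysis was possible because each part had 1 library per assay and the labels pair none. Of 3514 alternative values over 413 results and 28 settings, 3139 stayed within the counting interval of the reported value, 320 moved outside it, 37 of them to the other side of 0, and 55, of 42 results whose interval left out 0, changed sign. Of the values within the interval, 82 also lay on the other side of 0. All 36 values for windows stayed. In hair-cell-like cells the early list ranged from 0.28 to 0.49, the later list from −0.61 to −0.15 and the bundle list from −0.35 to −0.13. These ranges leave out the shared sub-cluster, where the early list was at −0.28, the later list at 0.41 and the bundle list at 0.04. In supporting-cell-like cells the FGF list ranged from −0.68 to −0.20, the heterochronic list from 0.30 to 1.41, the tectorial list from −0.65 to −0.19 and the Notch list from −0.10 to 0.28. The 3 motif alternatives were not run, since no genome sequence was at hand. Depth limited what could be seen: 20 base hair-cell-like cells and 51 base nuclei carry every base value of that class. For these 28 settings, every changed sign of a result whose interval left out 0 follows, with the moved values of the class shares, the correlations and the 7 lists above. Other moved values are given as counts only. The comparison within the shared sub-cluster is not among the settings. It turned the early, later and immediate early lists of the hair class, among others, as given with the results. The cause was not tested except where it is given.

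In RNA, a finer clustering (resolution 2) gave inner-hair-cell-like cells 50% of the base class. At least 3000 UMIs and at most 10% mitochondrial UMIs gave Deiters shares of 53.9% and 41.4%, a base supporting share of 12.4%, a tectorial list of −0.19 and Lum at 2.72. Cells thinned to 5000 UMIs gave a later list of −0.18, bundle −0.13, immediate early −0.0595, outer hair cell markers 0.0515 and ribosomal −0.0629 in the hair class, and Fscn1 0.0671 in the supporting class, where counts fell and 89 of 115 apex and 37 of 56 base cells remained. The mean of per-cell CPM gave early 0.49, later −0.15 and ribosomal −0.0439 in the hair class, and FGF −0.20, Notch −0.0256, tectorial −0.33 and inner phalangeal markers −0.18 in the supporting class, with a rho between classes of 0.046. A minimum of 10 UMIs gave a rho of 0.058 and a tectorial list of −0.58, and one of 50 UMIs a rho of 0.123. Median-of-ratios scaling gave −0.00192 for the ribosomal list in the hair class. Without mixed cells it was −0.0302. Without inner-hair-cell-like cells, Fgf8 was at −1.53 and Nefl at −0.0816, since those cells held most of their RNA. Equal subtype weight gave −0.0192 for transcription factors in the supporting class. Deiters-like cells alone gave FGF −0.68, Notch −0.10, heterochronic 0.30, tectorial −0.65, Lgr5 0.11, Lum 1.38 and Npy 3.85 (31 and 0 UMIs, so no fold).

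In accessibility, a minimum of 10000 fragments gave a base supporting share of 25.7%, Cd300lf 0.49, Cdh5 0.0122, Cyp2b10 0.10, Ifi208 0.35, Mitf 0.25 and Wdr49 1.27 in the supporting class. Without nuclei over 100000 fragments, Cd300lf was at 0.0349, Cdh5 0.30, Ifi208 1.60, Klra17 0.20, Mitf 0.15 and Wdr49 0.56, since 6 base nuclei held 42.2% of the base fragments of the supporting class. Gene ends in place of bodies gave an early list of −0.0152, Tmc1 3.67 (0 base fragments, so no fold), Fzd3 −0.22, Otoa −0.0143, Otog −0.0387, Rspo2 0.18 and Slc26a5 0.19 in the hair class, and Bmp7 −0.41, Lgr5 −0.00794, Pax3 −0.11 and Ptprq −0.36 in the supporting class. They also gave a rho between RNA and accessibility of 0.086 in the hair class, and of 0.425 (apex) and 0.334 (base) for the hair-to-supporting difference. A minimum of 50 counts gave 0.179 and, for the base difference, 0.515. The hair-cell-like cluster with most base nuclei gave early −0.0943, hedgehog −0.0268, cytoskeleton −0.0555, Ntf3 −0.0304 and Rprm 0.15. Deiters-like nuclei alone gave Wnt −0.0926, hedgehog 0.00998, glial markers 0.0937, Lum 1.35, Mitf 0.28, Pmp22 0.45, Slc17a8 −0.18, Slc1a3 −0.0191, Tyms −0.22 and Wdr49 0.27. At the base, 14 of these 22 nuclei came from the Deiters-like cluster of less sure name.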

Other observations

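Of the tests in this part, all were chosen after the results were seen.

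Some apex hair-cell-like cells held much RNA of Nnat, Mdk and Stmn1. In the 11 apex cells of 1 unnamed sub-cluster, Nnat was at 4065 CPM and had UMIs in all of them, while the inner-hair-cell-like cells of the apex had 252 CPM, the 11 apex cells of the other unnamed sub-cluster 341 CPM and the 15 outer-hair-cell-like cells of the base 0. Chrng followed another course, with 515 CPM in the 6 inner-hair-cell-like cells and 282 CPM in the 11 cells. Nnat had 20 and 35 UMIs in apex and base glial-like cells. A hypothesis was that these genes mark the less mature cells within the apex. Among apex hair-cell-like cells without inner-hair-cell-like and mixed ones, the 12 cells richer in Nnat, Itih5, Mdk, Chrng and Stmn1 had a later hair cell list of −1.27 (−1.46 to −0.80) against the 12 others. Their early list was at 0.58 (0.39 to 0.83), the bundle list at −0.54 and the mitochondrial list at −0.42, while outer hair cell markers were at −0.42 (−1.17 to 0.14) and the cell cycle list at 0.02. Both groups came from 1 library with median UMIs of 24449 and 26537, so the library did not set them apart and their depth differed little. The 5 genes may mark immaturity, found and tested on the same cells, but the richer and the other cells mostly fell in separate sub-clusters, so a difference in the kind of hair cell stays open. In the sub-cluster shared by 11 apex and 5 base cells, Nnat had 87 and 2 UMIs, while Stmn1 had 24 and 15 (94.0 and 95.8 CPM).

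Nfix and Crabp2, both chosen after their values were seen, lay on 1 side in both classes. Nfix was base-higher in hair-cell-like cells (1 and 56 UMIs) and in all 4 supporting subtypes. All 56 base UMIs lay in the outer-hair-cell-like sub-cluster, with 15 of 20 base and 2 of 33 apex cells. The hair cell side may thus follow the sub-cluster, by kind of cell or by maturity, which cannot be told apart here. The later list may do the same, at 0.41 in the shared sub-cluster, where Nfix had 0 UMIs. Of the other classes, glial-like (16 and 18 UMIs), endothelium-like (22 and 19) and mesenchyme-like cells (466 and 235, log2 ratio −0.14) showed little difference in Nfix. Crabp2 was apex-higher in hair-cell-like cells (21 and 1 UMIs) and in the 4 subtypes, and mesenchyme-like cells had 64 and 44 UMIs of it (−0.59). Of the apex hair-cell-like UMIs of Crabp2, 17 lay in 4 cells of the unnamed sub-cluster that held apex cells alone. The shared sub-cluster had 2 and 0, so this side too may follow the sub-cluster. Genes of the same kind in the supporting subtypes were Col11a2 (−1.38), Sdc4 (−1.27), Cd9 (−1.37) and Fam3c (−1.34) at the base and Hist3h2ba (0.77) at the apex. Nr2f2, apex-higher in supporting-cell-like cells, was at 0.29 in glial-like and −0.08 in mesenchyme-like cells.

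A few base glial-like cells held neuron RNA. The neuron markers had a median of −5.77 in glial-like cells (−4.06 with genes at 0 set to their bound), with 8 of 8 base-higher. Nefl had 2 UMIs in the apex and 129 in the base, Nefm 1 and 110, Isl1 0 and 50 and Pvalb 2 and 280. Of 56 base glial-like cells, 2 held at least 10 UMIs of 4 neuron genes, with a median of 38467.5 UMIs per cell, and of 69 apex ones 0 did.

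The unnamed accessibility cluster led by Fgfr2, with 20 apex and 61 base nuclei, could hold cells like Hensen, Claudius and outer sulcus cells. Its gene activity gave a Spearman's rho of 0.331 across 3274 genes with the RNA cluster of that name and 0.320 with the unnamed RNA cluster, so it cannot be told apart which of both it matches.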
